A study of Homo sapiens with 3 samples.

How the data were processed

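Libraries came from HEK293T cells infected at a multiplicity of 5 particles per cell with 8 µg/mL polybrene and collected after 72 hours, per the labels' protocols. RNA was poly(A)-selected, prepared with an MGIEasy kit and sequenced as 100 bp paired-end reads on a DNBSEQ-G400. The control carried the pLKO.1 vector and each knockdown library 1 of 2 hairpins, so the groups held 1 and 2 libraries. Nothing states whether the cultures were separate, so p-values measure only the spread between these libraries.

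The authors deposited whole-number counts per gene, not normalized. STAR 2.7.3a, DESeq2 1.26 and the build GRCh38 (hg38) are named in the submitters' processing notes. The read counter, its strand setting and the annotation release are not given in the sources used here, so genes that overlap on opposite strands cannot be told apart. The table held 67008 gene models, 60609 on chromosomes and 6399 on other scaffolds. Of its versioned identifiers 41838 were shared with GENCODE release 29, and 100% of those had the same coordinates. Treatment of reads that match several places affects genes with copies on alternate scaffolds, overlapping genes and pseudogenes; values for such genes are uncertain.

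Counts were filtered with filterByExpr (minimum count 10), which left 17713 genes, and scaled by TMM. The main test was edgeR 4.0.16 quasi-likelihood (glmQLFit with legacy = FALSE, glmQLFTest) with Benjamini-Hochberg adjustment at 0.05, in R 4.3.3. The residual spread has 1 degree of freedom and comes only from the difference between the hairpins; the lone control library is assumed to vary likewise. Standard errors are the log2 fold change divided by the square root of F. Log2 ratios per library used a prior count of 2, and their intervals are exact Clopper-Pearson intervals at 95%, which cover counting error only. A count of 0 was given a floor of 3 counts.

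Before the data were examined, 28 gene lists were fixed and the rule for named genes was set. The rule takes DDX24 and HMOX1, the 10 highest and 10 lowest genes by the smaller of the absolute log2 ratios of both hairpins at 5 CPM or more in at least 1 library, passing genes first, up to 4 members per list by the same ranking, genes of the study's theme, and the 5 genes most different between hairpins in each direction. Fewer than 10 genes passed in either direction, so most places were filled by genes that did not pass. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 over lists with at least 5 members tested, adjusted over the 28 lists. Some genes and 1 of the lists, which passed, are not reported here. None of the 8 list calls held with an estimated correlation. That setting tests on the 1 residual degree of freedom, so few lists could pass, and it cannot decide on the calls. Of the list members, 13 were found through an older symbol.

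The shared control was simulated with 100 draws of unchanged libraries at the estimated dispersion. On simulated data for the knockdown comparison (17713 genes, 200 changed, all at 5 CPM or more), edgeR recovered 82% of 2-fold and 100% of 4-fold and 16-fold changes, with 1, 2 and 9 false calls. Simulated genes followed the dispersion trend with no spread of their own, so recovery in the real libraries can be lower. There ANKRD1, at a log2 fold change of -2.38, did not pass. A list shifted by -0.3 was called (camera adjusted p = 6.76e-06) with 0 other lists called. Genes were drawn independently, so this check does not cover false list calls from correlation between genes. In the real libraries the estimated correlation was 0.50 for the mitochondrial transcripts. With 1 residual degree of freedom such an estimate reflects only which hairpin each member was higher with. An imposed GC trend with a slope of 2.00 was reduced to -0.01 by the correction described next.

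Alternatives were DESeq2 size factors, library totals, other filters, DESeq2 1.42.0, limma-voom, the legacy quasi-likelihood fit, an adjusted p of 0.1, other fold, CPM and prior count limits, an estimated correlation, and leaving out each hairpin. After the data were seen, removal of a loess trend on GC content and transcript length and thinning of the control to the mean hairpin depth were added.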

Results

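Gene expression was measured by poly(A)-selected RNA sequencing in HEK293T cells, a human embryonic kidney line that carries the SV40 large T antigen, 72 hours after infection with lentivirus. The 3 libraries comprised 1 control infected with the pLKO.1 vector and 2 DDX24 knockdown libraries, 1 for each of 2 short hairpin RNAs, here called hairpin 1 and hairpin 2. DDX24 is a DEAD-box RNA helicase, and the series concerns its part in the transcriptional control of HMOX1, which encodes heme oxygenase 1, the enzyme that degrades heme. The control library held 52198744 counts, the hairpin 1 library 36738685 and the hairpin 2 library 37828270. At least 1 count was found for 28020, 26370 and 25954 gene models, respectively. Mitochondrial transcripts took 3.51% of the counts in the control and 4.21% and 3.80% with hairpin 1 and hairpin 2.

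The targeted gene was examined first. DDX24 (ENSG00000089737.17, GRCh38 chromosome 14, 94048287 to 94081212, minus strand) was listed at 0 counts in all 3 libraries, the control included. Its second gene model, on an alternate scaffold (ENSG00000273761.5), was also at 0 in all 3 libraries. A count of 0 allows up to 0.0575 CPM (counts scaled to library size) in the control and 0.0817 and 0.0793 with hairpin 1 and hairpin 2, for counting error only. Other genes that growing cells use were at 0 as well, among them FBL, a nucleolar methyltransferase, the ribosomal protein genes RPL7A and RPS18, and the respiratory complex I genes NDUFS1 and NDUFA6. Of 1112 protein-coding genes with a copy of the same symbol on another scaffold, 806 (72.5%) were at 0 in all 3 libraries, against 2999 of 18853 (15.9%) without one. The knockdown could therefore not be measured, and the library labels could not be checked against their target.

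HMOX1 (ENSG00000100292.17, chromosome 22, 35380361 to 35394207, plus strand) was at 91.3 CPM in the control, 49.2 with hairpin 1 and 50.0 with hairpin 2. The log2 ratio to the control was -0.89 with hairpin 1 (95% exact binomial interval of the counts, -0.97 to -0.81) and -0.87 with hairpin 2 (-0.95 to -0.79). The knockdown mean was 49.6 ± 0.56 CPM (SD, n = 2). Across the group the log2 fold change was -0.88 ± 0.13 (SE), which did not pass the edgeR quasi-likelihood test over all genes (adjusted p = 0.873), although HMOX1 ranked 6 of 17713 genes by p. Adjusted over the list alone, HMOX1 passed among the NRF2 targets (adjusted p = 0.0083) and among the heme and iron genes (adjusted p = 0.0089). The same fold passed over all genes with DESeq2 (adjusted p = 0.0128) and with scaling by library totals (adjusted p = 0.0178), but not with limma-voom (adjusted p = 0.997) or with DESeq2 size factors in edgeR (adjusted p = 0.968).

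**Figure D1:**
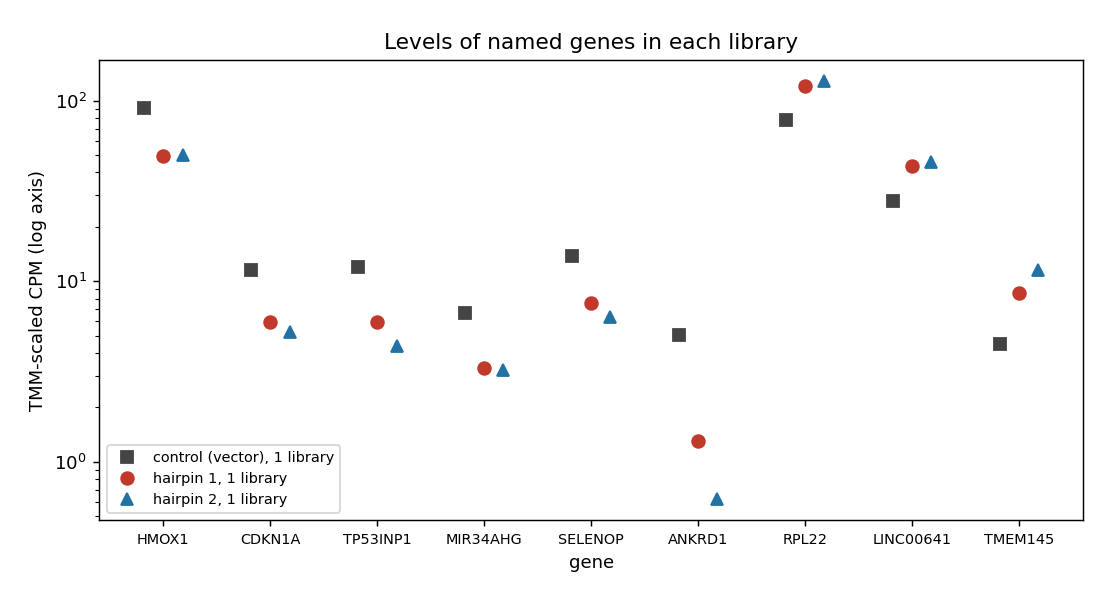
TMM-scaled CPM (log axis) of 9 named genes in the control library (squares), the hairpin 1 library (circles) and the hairpin 2 library (triangles), each point 1 library. HMOX1 stood at 91.3 CPM in the control and at 49.2 and 50.0 with the hairpins; of the genes drawn none passed the planned edgeR test over all genes.

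Few genes separated the knockdown libraries from the control. The small nuclear RNA gene RNU6-1 (chromosome 15, 67839939 to 67840045, minus strand) was at 2452 counts in the control, 13 with hairpin 1 and 9 with hairpin 2. Its log2 fold change was -7.27 ± 0.25 (SE, edgeR adjusted p = 0.00051). Reads from the vector were not excluded as the source of these counts. AC243919.1 (chromosome 15, 82372196 to 82372912) fell from 168 counts to 2 and 1, with a log2 fold change of -6.20 (adjusted p = 0.040). It lies outside the rule for named genes and was named after its values were seen. Of 17713 genes tested with edgeR, these 2 were lower and 0 were higher at an adjusted p of 0.05. At an unadjusted p under 0.05 there were 688 genes, 248 higher and 440 lower, where chance alone gives 886. DESeq2 called 3 genes and limma-voom 1, all lower. The RNU6-1 call was lost with DESeq2 size factors (adjusted p = 0.376) and without the low-count filter (adjusted p = 0.304). AC243919.1 was called with DESeq2 (adjusted p = 0.00014) and with library totals in edgeR (adjusted p = 6.74e-05). It was also called with the GC and length trend removed, in a fit whose spread was shared across genes. It was not called with DESeq2 size factors in edgeR, limma-voom, the legacy fit or the thinned control, or without the low-count filter.

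The other lower genes named by rank did not pass the planned edgeR test over all genes. ANKRD1, a nuclear ankyrin-repeat protein induced by YAP signalling, was at 5.02 CPM in the control and at 1.30 and 0.62 with hairpin 1 and hairpin 2. It was called lower with library totals (adjusted p = 0.0178) and with the GC and length trend removed (adjusted p = 1.74e-09). CDKN1A, the cyclin-dependent kinase inhibitor p21, was at 11.6 CPM in the control and at 5.93 and 5.23 with the hairpins. TP53INP1, a stress-induced nuclear protein, was at 11.9 against 5.98 and 4.37 CPM, and MIR34AHG, the host transcript of miR-34a, at 6.63 against 3.30 and 3.21 CPM. SELENOP, a secreted selenium carrier, was at 13.8 against 7.55 and 6.36 CPM. With that trend removed, TP53INP1 (adjusted p = 0.0016), CDKN1A (adjusted p = 0.0042) and SELENOP (adjusted p = 0.036) were also called lower, in a fit whose spread was shared across genes. The histone genes HIST1H2AC and HIST1H3E and the ciliary gene CFAP70 had log2 fold changes of -0.98, -0.94 and -0.95. Histone genes have close copies, so reads can be divided among them.

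Among genes higher with both hairpins, RPL22, a protein of the large ribosomal subunit, was at 78.0 CPM in the control and at 120 and 129 with hairpin 1 and hairpin 2. The long noncoding RNA LINC00641 was at 27.7 against 43.3 and 45.8 CPM. TMEM145, a membrane protein gene, was at 4.51 against 8.60 and 11.5 CPM, and MT2A, a metallothionein that binds zinc and copper, at 4.07 against 6.66 and 6.93 CPM. GNAO1, a G protein subunit, and CPLX1, a complexin of synaptic vesicle release, had log2 fold changes of 0.91 and 1.08; without hairpin 2 that of CPLX1 was 0.68. HIC1, a transcriptional repressor, SBK1, a kinase, the small RNA gene BCYRN1 and the ribosomal protein pseudogene RPSAP47 had log2 fold changes of 0.80, 0.68, 0.85 and 1.02. None of these 10 passed the planned edgeR test (adjusted p = 0.999 for each). With the GC and length trend removed TMEM145 was called higher (log2 fold change 1.14, adjusted p = 0.0081), the 1 gene called higher in that fit. The spread in that fit was shared across genes. RPSAP47, BCYRN1 and MT2A have close copies elsewhere in the genome and are uncertain for that reason.

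By size alone, RNU6-1 and ANKRD1 were at least 2-fold lower with both hairpins, and 0 genes were at least 2-fold higher with both, among 10995 genes at 5 CPM or more in at least 1 library. This rule involves no test. With hairpin 1 alone 3 genes were 2-fold higher and 6 lower, and with hairpin 2 alone 7 were higher and 43 lower. Simulated libraries with no effect and a shared control gave a mean of 0.05 lower and 0.18 higher genes (at most 1 of each in 100 draws). Simulated genes followed the dispersion trend with no spread of their own, so these means can be too low. Independent lists of the sizes found with each hairpin alone, which leave out the shared control, would share 0.0235 lower genes and 0.0019 higher genes. At a minimum of 1 CPM, 27 genes met the rule, 4 higher and 23 lower.

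The log2 ratios of the hairpins correlated across those 10995 genes with Pearson's r of 0.424 and Spearman's rho of 0.372, where genes are not independent replicates. Both ratios share the control library, and simulated libraries with no effect gave a mean r of 0.491 (0.474 to 0.510 over 100 draws) and a mean rho of 0.472. The observed covariance was 0.0218 against 0.0281 in the simulation, a difference of -0.0062. Ratios had the same sign for 62.9% of genes, against 66.5% in the simulation. The simulated spread did not match these libraries: the SD of the ratios was 0.204 with hairpin 1, against 0.239 simulated (0.233 to 0.244), and 0.252 with hairpin 2, against 0.239 (0.235 to 0.243). The part of the agreement that comes from the shared control was therefore not settled, and the control, as 1 library, could not be split.

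**Figure D2:**
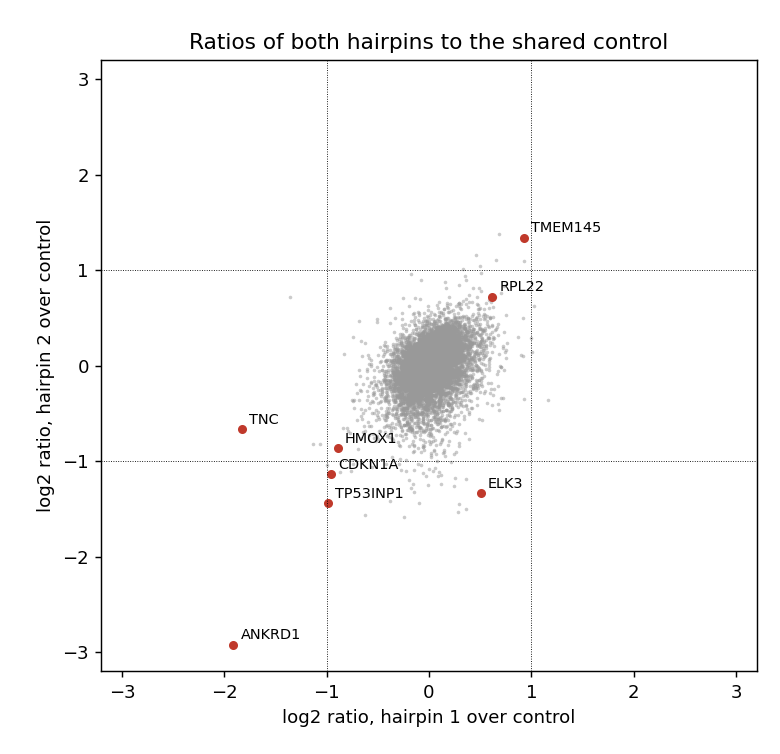
Log2 ratio to the control with hairpin 1 (x axis) and hairpin 2 (y axis) for 10995 genes at 5 CPM or more in at least 1 library, each point 1 gene, with dotted lines at 2-fold and named genes in red. RNU6-1 lies outside the axes; across genes r was 0.424, against 0.491 in simulated libraries with no effect.

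The hairpins also differed from each other. ELK3, an ETS transcription factor, was at 36.2 CPM with hairpin 1 and 10.1 with hairpin 2, with 25.5 in the control. RASSF2, HABP4, PRX and USH1C were likewise higher with hairpin 1, with log2 ratios of hairpin 2 to hairpin 1 of -1.86, -1.82, -1.73 and -1.54. Their log2 ratios to the control were 0.28 to 0.36 with hairpin 1 and -1.54 to -1.18 with hairpin 2, so the larger departure was the drop with hairpin 2. Higher with hairpin 2 than with hairpin 1 were PLXNA2, a semaphorin receptor, AP2A2, an adaptor subunit of endocytosis, the mitochondrial tRNA genes MT-TS1 and MT-TQ, and TNC, the matrix protein tenascin C. TNC was at 8.67 CPM in the control, 2.41 with hairpin 1 and 5.44 with hairpin 2, below the control with both. It was called lower with the GC and length trend removed (adjusted p = 0.0052), in a fit whose spread was shared across genes. In the planned edgeR test TNC was not called (adjusted p = 0.999). In all, 52 genes differed at least 2-fold between the hairpins, 47 higher with hairpin 1 and 5 higher with hairpin 2, with no replicate check. The SD of the log2 difference over genes was 0.248 between the hairpins, 0.204 between the control and hairpin 1, and 0.252 between the control and hairpin 2.

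Targets of NRF2, the transcription factor of the oxidative stress response, did not pass as a list. Of 28 tested, 10 were lower and 8 higher with both hairpins (camera adjusted p = 0.180). Over all genes 0 fell or rose by edgeR, with 3 at an unadjusted p under 0.05; adjusted over the list alone 1 fell, HMOX1. SLC7A11, the cystine transporter, had a log2 fold change of -0.56, ME1, malic enzyme, -0.32, and NQO1, a quinone reductase, -0.20. For other members the ratios are given by hairpin, with 1 library each and no test between the hairpins. The log2 ratios with hairpin 1 and hairpin 2 were -0.18 and -0.53 for TXNRD1, thioredoxin reductase, lower with both. They were 0.22 and 0.48 for SRXN1, sulfiredoxin, which had 40 counts in the control and 33 and 40 with the hairpins. The exact binomial intervals for SRXN1 were -0.47 to 0.94 and -0.16 to 1.18. These intervals overlapped and both included 0, so no difference between the hairpins was shown for SRXN1. The log2 ratios had opposite signs, -0.12 and 0.09, for GCLM, the modifier subunit of glutathione synthesis. Among the regulators they were -0.01 and -0.06 for NFE2L2, -0.11 and 0.07 for KEAP1, and -0.01 and 0.16 for BACH1, and the list of NRF2 regulators had a camera adjusted p of 0.316. None of these members passed the test.

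The heme and iron list, which also holds HMOX1, had 15 of 30 members lower and 5 higher with both hairpins (camera adjusted p = 0.067). Genes that detoxify reactive oxygen were mixed, with 12 of 33 lower and 10 higher (adjusted p = 0.765). SOD1 and SOD2, the cytosolic and mitochondrial superoxide dismutases, had log2 ratios of 0.00 and 0.12 (SOD1) and 0.10 and 0.32 (SOD2) with hairpin 1 and hairpin 2. Catalase, CAT, was at 0.13 and -0.11, with opposite signs.

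Neither list of apoptosis genes passed camera. Of 34 pro-apoptotic genes 14 were lower and 8 higher with both hairpins (camera adjusted p = 0.765), and of 20 anti-apoptotic genes 7 were lower and 7 higher (adjusted p = 0.788). The effector BAX had a log2 fold change of -0.16. With hairpin 1 and hairpin 2 the log2 ratios of the inhibitors were 0.08 and 0.22 for BCL2, 0.04 and 0.01 for BCL2L1, and -0.04 and 0.09 for MCL1. The initiator caspase genes CASP8 and CASP10 were at -0.30 and -0.51. In both lists 0 members passed edgeR over all genes or adjusted over the list alone, with 1 and 0 at an unadjusted p under 0.05, and DESeq2 and limma-voom called 0.

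Transcripts encoded by mitochondrial DNA were higher as a list, with 14 of 15 higher with both hairpins and median log2 ratios of 0.30 and 0.17 (camera adjusted p = 2.67e-06). MT-ND5, a complex I subunit, was at 1482 CPM in the control and at 2147 and 1907 with the hairpins. Ribosomal protein genes had 57 of 76 higher with both (adjusted p = 2.67e-06), with medians of 0.07 and 0.14, and RPS27 was at 608 against 729 and 730 CPM. Nuclear genes of oxidative phosphorylation had 28 of 53 higher (adjusted p = 0.0073), among them ATP5ME, an ATP synthase subunit, at 81.6 against 115 and 114 CPM. Each of these 3 calls was lost with an estimated correlation (camera adjusted p = 0.900). The estimated correlations were 0.50, 0.21 and 0.06, above the preset 0.01, so the p-values at the preset can be too small. That setting also tests on 1 residual degree of freedom, so the part of the loss due to correlation cannot be told. In each list 0 members passed edgeR, over all genes or adjusted over the list alone, with 4, 2 and 1 at an unadjusted p under 0.05; DESeq2 and limma-voom called none of the members named here.

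Hypoxia and glycolysis genes (16 of 32 higher with both, adjusted p = 0.0073), matrix and adhesion genes (13 of 32, adjusted p = 0.026) and immediate early genes (16 of 26, adjusted p = 0.045) also passed camera upward. Median log2 ratios with hairpin 1 and hairpin 2 were 0.02 and 0.17 for hypoxia genes, 0.12 and 0.03 for matrix genes, of which 17 were mixed, and 0.14 and 0.10 for immediate early genes. Among 10000 random lists matched on mean expression, these medians were at percentiles 75.0 and 99.99 (hypoxia) and 99.7 and 62.3 (matrix). Those of the immediate early genes were at 98.8 and 95.8. The hypoxia and matrix lists thus stood out with 1 hairpin each. Without hairpin 2 the mean of the hypoxia list went from 0.12 to 0.07. Examples were NDRG1, a hypoxia-induced gene, with log2 ratios of 0.36 and 0.70 with hairpin 1 and hairpin 2, PDK1, a kinase that limits pyruvate oxidation, with a log2 fold change of 0.40, CCN2, a connective tissue growth factor, with 0.42, and JUND, an AP-1 subunit, with 0.47. The list of nuclear-retained and non-polyadenylated RNAs passed camera downward (adjusted p = 0.026), with 7 of 11 lower and 4 higher with both hairpins. Its medians were -0.33 and -0.49. HIST1H2AC, HIST1H1C and KCNQ1OT1, an imprinted antisense RNA, fell when adjusted over that list alone (adjusted p = 0.041 for each in edgeR). All 4 calls were lost with an estimated correlation (camera adjusted p = 0.900), which tests on 1 residual degree of freedom. That correlation was 0.29 for hypoxia genes, 0.07 for matrix genes and 0.02 for immediate early genes, above the preset 0.01. For the nuclear RNA list it was -0.09, below the preset, so the loss there cannot be credited to it. The nuclear RNA call was also lost with DESeq2 size factors (adjusted p = 0.059) and with a GC and length trend removed (adjusted p = 0.058), and the immediate early call with that trend removed (adjusted p = 0.161).

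**Figure D3:**
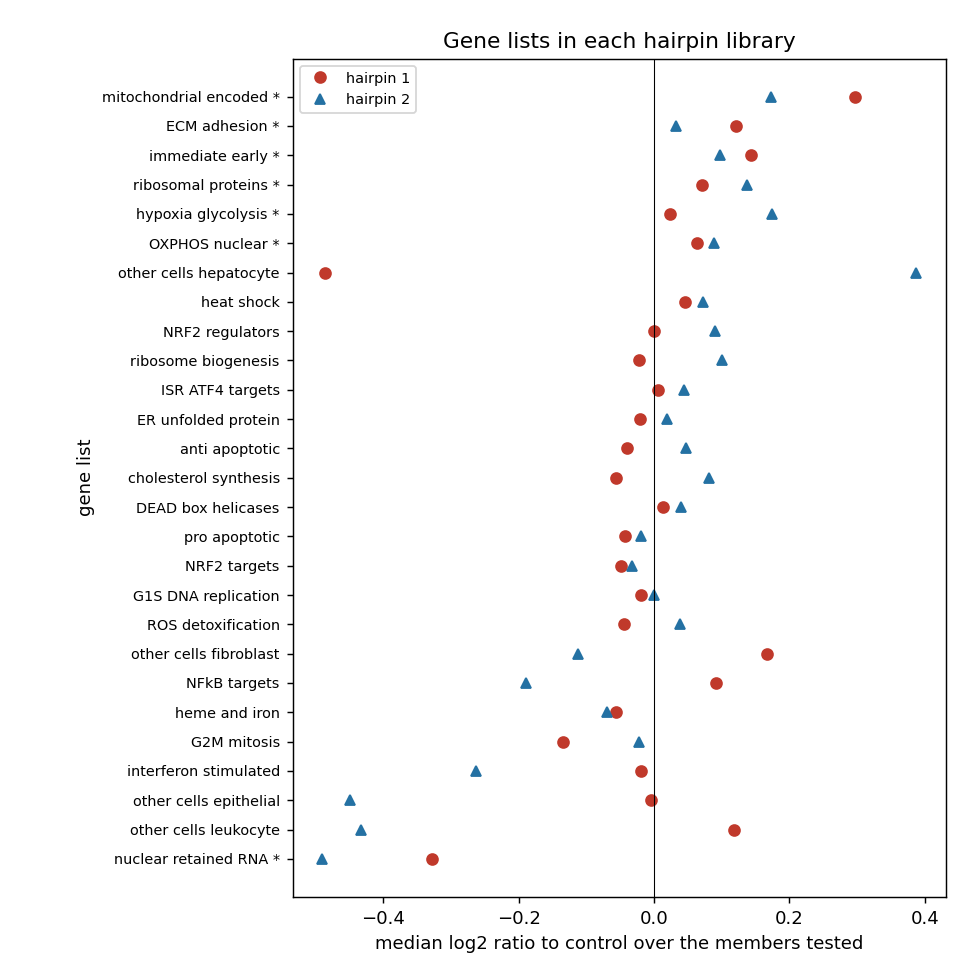
Median log2 ratio to the control (x axis) over the tested members of each of 27 gene lists (y axis), with hairpin 1 as circles and hairpin 2 as triangles; asterisks mark the 7 lists that passed camera with a preset correlation. The mitochondrial transcripts lay at 0.30 and 0.17.

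The remaining lists did not pass camera. Mitosis genes had 18 of 37 lower and 6 higher with both hairpins (adjusted p = 0.076). That list passed with scaling by library totals (adjusted p = 0.030), while with the GC and length trend removed its adjusted p was 0.283 and its mean log2 ratio went from -0.07 to -0.01. The mean was -0.04 without hairpin 1 and -0.10 without hairpin 2. Interferon-stimulated genes had 13 of 32 lower and 5 higher (adjusted p = 0.122), including SAMD9 and DTX3L at log2 fold changes of -0.63 and -0.52. The mean log2 ratio of that list was -0.30 without hairpin 1 and 0.003 without hairpin 2, so its lower mean rested on the hairpin 2 library. Ribosome biogenesis genes had an adjusted p of 0.186, DNA replication genes 0.765, DEAD-box helicases 0.695, heat shock genes 0.691, NF-kappaB targets 0.691, ATF4 targets 0.765, genes of the unfolded protein response 0.765 and genes of cholesterol synthesis 0.979. Markers of other cell types gave 0.443 for epithelial cells, 0.555 for leukocytes, 0.691 for fibroblasts and 0.765 for hepatocytes. In each of these lists 0 members passed the planned edgeR test over all genes or adjusted over the list alone, with 0 to 3 at an unadjusted p under 0.05, and DESeq2 and limma-voom called 0. With the GC and length trend removed 1 member was called, the NF-kappaB subunit RELB (log2 fold change -1.29, adjusted p = 0.043). The spread in that fit was shared across genes.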

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

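No paired analysis was possible because the control has 1 library. Leaving out a hairpin leaves 1 library against 1, with no test of genes or lists. Removal of the GC and length trend and thinning of the control were chosen after seeing the data. The log2 fold change of HMOX1 stayed between -0.92 and -0.86 in all fits, while its adjusted p ran from 0.00013 to 0.999. It passed with library totals (-0.91), DESeq2 (-0.88) and the GC and length trend removed (-0.92). The count of genes changed was 0 with DESeq2 size factors and 0 without the low-count filter. It was 1 each with the 5 CPM filter, the legacy fit, limma-voom and the thinned control, 7 with library totals and 22 (21 lower) with the trend removed. The prior degrees of freedom estimated by edgeR also moved: 5.67 in the main analysis, 0.911 without the filter, 2.40 with DESeq2 size factors, 4.602 with the thinned control, 4.79 in the legacy fit, 15.5 with library totals and infinite with the trend removed. It was 8.32 with the 5 CPM filter, which had 1 call. That filter removes AC243919.1 before testing, so its count cannot be compared with the others. An infinite value leaves no spread of a gene's own, so those 22 calls rest on a spread shared across genes.

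Genes 2-fold changed with both hairpins numbered 36 at 1.5-fold, 27 at 1 CPM and 1 at 20 CPM, and with 1 hairpin left out 9 to 50. Correlation of the hairpins was 0.467 at 1 CPM, 0.458 at 20 CPM and 0.365 without the 1% largest ratios. Genes different between hairpins numbered 359 at 1.5-fold and 5 at 3-fold. With an estimated correlation, tested on 1 residual degree of freedom, 0 of 28 lists passed. The counts under the other scalings and corrections were 6 to 9.

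Directions that reversed belonged to genes and lists that never passed. With library totals CAT was at -0.0101, MCL1 at -0.0027, MT-TS1 at -0.00031 and PLXNA2 at -0.0222. With limma-voom MT-TS1 was at -0.32 and PLXNA2 at -0.10, and with the 5 CPM filter PLXNA2 was at -0.0066. With the trend removed GCLM was at 0.0460 and BCL2L1 at -0.0048; with the control thinned BCL2L1 was at -0.0052, PLXNA2 at -0.0372 and ALB at -0.0203. The cholesterol list turned in camera with DESeq2 size factors (mean log2 ratio -0.0299), library totals (-0.0550) and the trend removed (-0.0304), and the unfolded protein list with the trend removed (0.0144). The cause of these reversals was not tested. Mean, median and camera differed in sign for the cholesterol, unfolded protein, heat shock, hepatocyte and pro-apoptotic lists.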

Other observations

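RPL22L1, the paralog of RPL22, was at 56.6 CPM in the control and at 51.3 and 26.5 with hairpin 1 and hairpin 2. Its log2 ratios were -0.14 and -1.10, so the drop was mainly in the hairpin 2 library. It did not pass the planned edgeR test over all genes and was named after its values were seen.

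All tests here were chosen after the data were seen; for depth and for GC content and length, the bounds on HMOX1 were set before those results were computed. DDX24 was listed at 0 in the control too, and those 0 counts argue against knockdown of DDX24 as the cause of its absence. Among genes of the ribosome, respiratory chain and cell cycle lists, 58.3% of the 12 with a copy on another scaffold were at 0, against 0 of 264 without one (two-sided Fisher's exact p = 3.53e-11). All 21 chromosome copies of protein-coding genes on the alternate locus that holds DDX24 were at 0. This is consistent with reads shared with a copy on an alternate locus being left uncounted, as a hypothesis; recounting from reads was not done here.

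RNU6-1 took 79.7% of all counts on RNU6 genes in the control, 2.50% with hairpin 1 and 1.75% with hairpin 2. The other 1434 RNU6 genes together were at 11.95 CPM in the control and at 13.8 and 13.3 with the hairpins, a log2 ratio of 0.18. Counts at those loci were thus not higher in the control. Reads shared between close copies may go uncounted, so these loci cannot decide on the amount of U6 RNA. Reads from the vector stay open as a candidate source; the vector sequences are not used here, and the value of 79.7% does not decide it. No biological explanation was tested.

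HMOX1 was lower with both hairpins. Its log2 fold change of -0.88 was -0.92 with the GC and length trend removed, which argues against that trend as the whole cause of its lower level. With the control thinned it was -0.86, which does not decide on library depth, since thinning leaves the expected ratio of an abundant gene as it was. A control library that stands apart cannot be told apart from an effect of the knockdown, because both ratios share 1 control library. An effect of DDX24 knockdown stays among the open explanations, untested without a measured DDX24 level or a second control.

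Splitting the 3 libraries otherwise, each of the 3 splits called 2 or more genes, the real one calling 2, and the highest other count was 242, with the hairpin 2 library alone against the control and hairpin 1. With 3 splits no share under 0.05 is possible. In the split with hairpin 2 alone the spread comes from the control and hairpin 1, the closest pair of libraries (SD of log2 differences 0.204, against 0.252 and 0.248). Whether the count depends on which pair supplies the spread was not tested. Of the 28 lists, the real split called 8 with camera at the preset correlation, hairpin 2 alone 7 and hairpin 1 alone 3.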
